A study of Ambystoma mexicanum with 8 samples.

How the data were processed

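Jaw tissue of juvenile axolotls (Ambystoma mexicanum, a salamander that regrows amputated body parts) was profiled by poly(A)-selected RNA sequencing. Per the labels' protocols, the animals measured 5 cm, the jaw was cut 5 mm from the midline, and single-end reads of 75 nt were sequenced from fragments of about 300 bp. The series holds 8 libraries: 4 of jaw removed at surgery and 4 of jaw regrown for 5 weeks. The sample titles carry the numbers 2, 3, 6 and 11 in both groups, which were taken as the animal each library came from.

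The authors deposited 1 table of raw read counts, with 1 row per transcript identifier and 1 column per library. The values were whole numbers that had not been normalized. The aligner, the counter and the reference sequences were not given in the sources used here. Per the submitters' processing notes, DESeq and DESeq2 were used by the authors, with no version or role given. The table had 18035 rows, none at 0 in every library and none repeated. All identifiers began with ENSXETT. The sources used here do not say which species' sequences they stand for, so a row is called a transcript after its identifier, and whether it measures 1 axolotl transcript was not tested. The file does not pair them with gene names, and 0 of them occurred in the RefSeq gene table supplied for the axolotl assembly UKY_AmexF1_1. Gene symbols, genomic positions and gene annotations are therefore not given here. The 23 gene lists fixed before the data were examined (cartilage, bone, muscle, teeth, nerve, blood, immune cells and others) matched 0 rows, so no list was tested, nor was the normalization planned without the muscle and erythroid lists.

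The total count ranged from 714809 to 2519291 in 7 libraries and was 489 in the pre-surgery library of animal 11. A count of 3, used as the detection floor, equals 1.19 to 4.20 CPM (a row's count per 1000000 counts of its library) in the 7 deep libraries and 6135 CPM in that library. Means and standard deviations of pre-surgery CPM therefore use the 3 deep libraries, while the planned test keeps all 8. Intervals and floors cover counting error only. Nothing in the labels beyond the animal numbers says that samples were processed independently, so p-values measure the spread between these samples.

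The planned comparison was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of regenerated against pre-surgery jaw. It used TMM normalization, edgeR's filterByExpr (minimum count 10, minimum total count 15) and Benjamini-Hochberg adjusted p at most 0.05. No term for the animal was included, since the sources used here do not state one. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The fit with the animal as a replicate block was planned beside it. The block was checked on the 3 animals with 2 deep libraries. Deviations from the group means over 4089 transcripts correlated at r = 0.09 in animal 2, 0.19 in animal 3 and 0.17 in animal 6. Libraries with different numbers gave r from -0.14 to -0.02. Both sets of values use the same group means, so they are not independent. The numbers were treated as pairing the samples, from the titles.

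The comparison was also repeated with DESeq2 1.42.0 with and without the block, DESeq2 size factors or library totals in edgeR, limma-voom (limma 3.58.1), other low-count filters, an adjusted p at most 0.01, edgeR's glmTreat against a fold of 1.5, and with each library left out in turn. Alternatives that combined the removal of the pre-surgery library of animal 11 with another setting, a filter of 10 counts in 3 libraries, and a table reduced to 1 row per set of near-identical rows were chosen after seeing the data. Rows were called near-identical when each of the 8 counts differed by at most 10% or 3 reads, for rows of at least 200 reads in total. Rows linked through another row joined the same set, so rows of a set can differ by more.

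Transcripts were named by a rule fixed before the data were examined. It took the largest fold changes among calls with a mean of at least 50 counts in the higher group and the same sign in all 4 animals, at most 2 identifiers per direction. Of the calls, 37 higher and 1 lower met it. The sign in animal 11 was set by the near-empty library, where a transcript with 0 counts cannot appear lower after regeneration. In animals 2, 3 and 6 alone, 37 higher and all 12 lower calls met the rule. A second lower transcript was chosen after its values were seen, by the same rule with animal 11 left out of the sign condition.

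The test was tried on simulated data with 200 changed rows among those tested, 5 times per design. With the depths of all 8 libraries, 52.0% of rows changed 2-fold were recovered. Of rows raised 4-fold, 99.3% were recovered, against 52.7% of rows lowered 4-fold. At 8-fold, 100% of rises and 29.2% of falls were recovered, and 8.27% of calls were false on average. Without the pre-surgery library of animal 11, 41.9% of 2-fold changes, 99.2% of 4-fold rises and 75.6% of 4-fold falls were recovered. At 8-fold, 100% of rises and 70.9% of falls were recovered, and 4.37% of calls were false. Rows that failed the low-count filter counted as not recovered.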

Results

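The series compared jaw tissue that had regrown for 5 weeks after amputation with the jaw tissue removed at surgery, in 4 axolotls. Each group held 4 libraries. The regenerated libraries held 724555 to 942477 counts. The pre-surgery libraries of animals 2, 3 and 6 held 714809, 758942 and 2519291 counts. The pre-surgery library of animal 11 held 489 counts on 181 rows, against 12067 to 15134 rows in the other 7 libraries. At that depth only the most abundant transcripts could be counted in it.

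**Figure D1:**
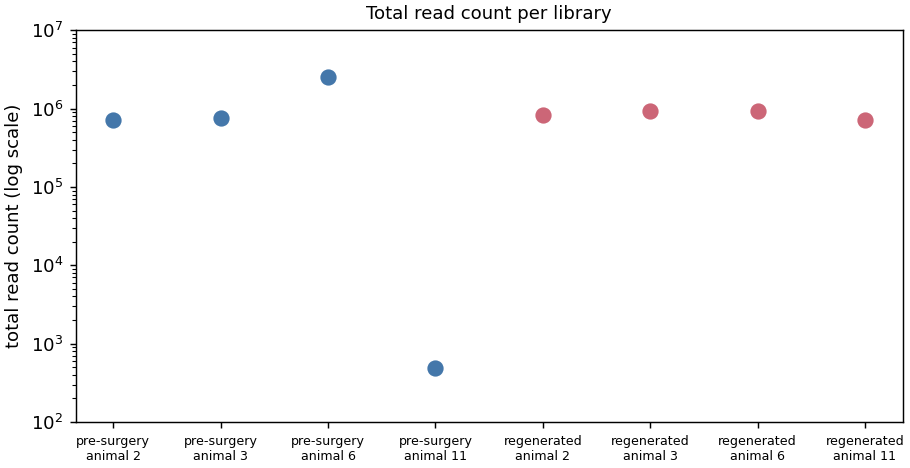
Total read count of each of the 8 libraries, on a log axis, by group and animal number; each point is 1 library. The 7 deep libraries lie between 714809 and 2519291 counts, and the pre-surgery library of animal 11 lies at 489.

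The libraries resembled one another before any test. Spearman's rho of log2 CPM across 4089 transcripts, which are not independent replicates, was 0.85 to 0.89 between deep pre-surgery libraries. It was 0.84 to 0.86 between regenerated libraries and 0.82 to 0.87 between the groups. The first principal component of the 7 deep libraries held 30.4% of the variance. The 3 pre-surgery libraries had the lowest scores on it, from -24.61 to -6.59. The regenerated library of animal 3 followed at -1.92, and the other regenerated libraries lay at 6.59 to 22.45. The number of transcripts detected at an equal total of 714809 counts was 11998 ± 161 (SD, n = 4) in regenerated jaw and 12025 ± 110 (SD, n = 3) in pre-surgery jaw. The difference was within the spread (exact two-sided permutation test over 35 reassignments, p = 0.83, Benjamini-Hochberg adjusted 0.83 over 3 measures). The smallest p this test allows is 0.029.

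Counts were concentrated on few transcripts in both groups. The 20 rows with the most reads took 40.8% ± 5.63 (SD, n = 4) of counts in regenerated jaw and 34.7% ± 1.76 (SD, n = 3) in the deep pre-surgery libraries. The difference was not past the spread of unpaired libraries (exact two-sided permutation p = 0.14, adjusted 0.43). Within animals the share was higher after regeneration in 3 of 3, by 11.1 percentage points in animal 2, 5.64 in animal 3 and 9.20 in animal 6. The exact sign-flip permutation test of these 3 pairs gave p = 0.25, the smallest it allows. The lowest regenerated share, 33.2%, was that of animal 11, which has no deep pre-surgery library. The single row with the most reads took 7.96% to 14.9% of counts in regenerated jaw and 8.32% to 10.9% in the deep pre-surgery libraries (exact two-sided permutation p = 0.34, adjusted 0.51), and it was also higher after regeneration in 3 of 3 pairs. In the pre-surgery library of animal 11 that row took 42 of 489 counts, or 8.59% (95% Wilson interval 6.42% to 11.4%). Some rows had equal counts. Among the 3587 tested rows, 599 had the same 8 counts as another tested row. Grouping near-identical rows left 3168 sets. Whether such rows shared reads was not tested.

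The comparison of regenerated with pre-surgery jaw asked which transcripts differ between the regrown and the original tissue. With all 8 libraries, 73 of 3587 transcripts passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p at most 0.05). Of these, 61 rose and 12 fell in regenerated jaw, and the 73 rows formed 66 near-identical sets. The transcripts that rose did so by a log2 fold change of 0.84 to 3.11, with a median of 1.30. Those that fell had log2 fold changes between -0.60 and -1.82, with a median of -1.45. An unadjusted p under 0.05 was reached by 505 transcripts, where 179 would be expected by chance. The median log2 fold change of all tested transcripts was 0.03.

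The count of calls depended on the near-empty library and on the pairing. Without the pre-surgery library of animal 11, 23 transcripts passed, 22 higher and 1 lower, and 21 of them were among the 73. With the animal as a replicate block, 239 transcripts passed with all 8 libraries, 140 higher and 99 lower, and these included all 73. With the block and without the near-empty library, where only animals 2, 3 and 6 inform the contrast, 116 passed, 69 higher and 47 lower. That paired fit shared 51 of its calls with the 73. None of the 73 transcripts changed sign under any of the alternatives that gave it a value. The alternatives reuse the libraries in which the 73 were chosen, so the kept signs are no independent support.

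**Figure D2:**
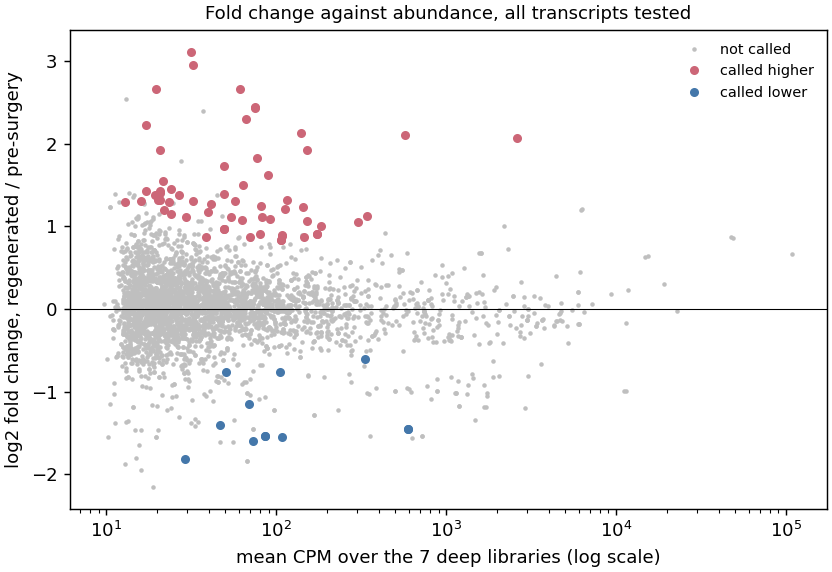
Log2 fold change (regenerated over pre-surgery, edgeR, all 8 libraries) against mean CPM over the 7 deep libraries on a log axis, for the 3587 transcripts tested. Coloured points are the 61 transcripts called higher and the 12 called lower at an adjusted p of at most 0.05; grey points were not called.

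The transcript that rose most under the naming rule was ENSXETT00000001084. It stood at 95.6 ± 38.6 CPM (SD, n = 4) in regenerated jaw and 14.7 ± 3.57 CPM (SD, n = 3) in the deep pre-surgery libraries. Its log2 fold change was 2.66 (SE 0.30), or 6.30-fold (edgeR adjusted p = 0.0023). The lowest regenerated library, at 49.9 CPM, lay above the highest pre-surgery library, at 16.8 CPM. The second was ENSXETT00000061287, at 114 ± 43.1 CPM (SD, n = 4) against 22.4 ± 4.68 CPM (SD, n = 3). Its log2 fold change was 2.44 (SE 0.33; edgeR adjusted p = 0.0023), and again the groups did not overlap (75.9 to 172 against 18.7 to 27.7 CPM). This row was near-identical to 1 other row, and the 2 rows are counted as 1 set. Both transcripts passed without the near-empty library, with edgeR adjusted p = 0.013 and 0.017. Both had 0 counts in that library, where 3 counts would equal 6135 CPM.

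Only 1 lower transcript met the naming rule, because 11 of the 12 lower calls had 0 counts in the near-empty library. ENSXETT00000062349 stood at 272 ± 27.5 CPM (SD, n = 4) in regenerated jaw and 416 ± 13.9 CPM (SD, n = 3) in the deep pre-surgery libraries. Its log2 fold change was -0.60 (SE 0.14; edgeR adjusted p = 0.045), and its groups did not overlap (240 to 306 against 403 to 431 CPM). It met the rule in animal 11 through 1 read in the near-empty library. Without that library its edgeR adjusted p was 0.047. It failed in 16 of 25 alternatives, while its log2 fold change stayed between -0.68 and -0.52. That count leaves out the adjusted p at most 0.01, glmTreat and the near-identical sets. ENSXETT00000053959, chosen after its values were seen, had the lowest log2 fold change among the calls, -1.82 (SE 0.38; edgeR adjusted p = 0.034). Its levels were 13.9 ± 5.99 CPM (SD, n = 4) against 49.4 ± 24.6 CPM (SD, n = 3). The pre-surgery library of animal 3, at 21.1 CPM, lay below the regenerated library of animal 2, at 22.7 CPM, but the level was lower after regeneration within each of animals 2, 3 and 6. Without the near-empty library this transcript did not pass (log2 fold change -1.85, SE 0.42, edgeR adjusted p = 0.10), and with the block it passed on all 8 libraries (edgeR adjusted p = 0.0034) and without the near-empty library (log2 fold change -1.70, edgeR adjusted p = 0.048).

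**Figure D3:**
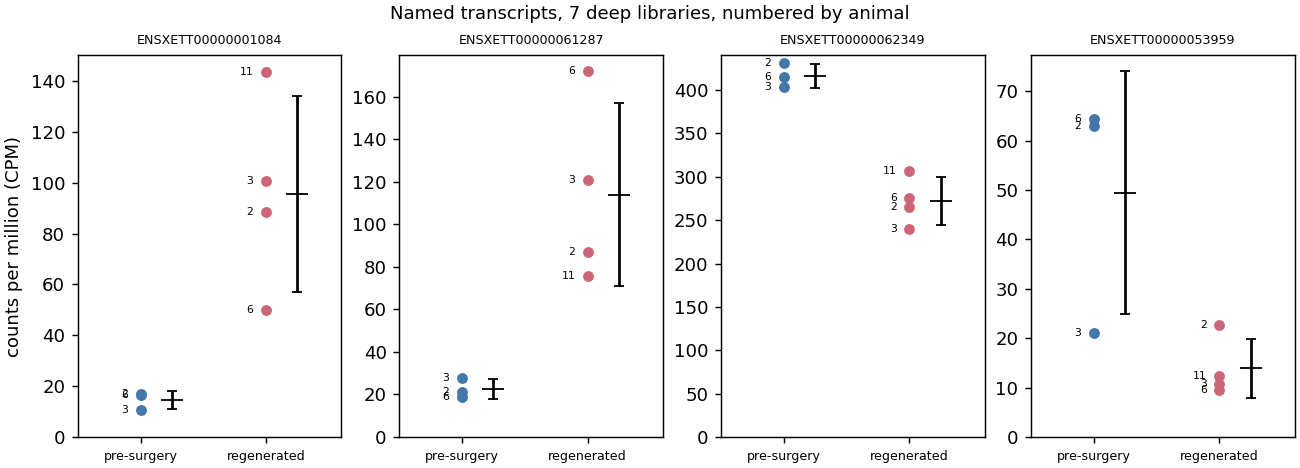
CPM of the 4 named transcripts in the 7 deep libraries; points are libraries labelled by animal number, and the bar beside them is the mean with its SD (n = 3 pre-surgery, n = 4 regenerated). ENSXETT00000001084 and ENSXETT00000061287 are higher in all 4 regenerated libraries, ENSXETT00000062349 is lower in all 4, and the groups of ENSXETT00000053959 overlap.

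A comparison by rank, which uses no model of the spread, was made on the 7 deep libraries. In 256 of 4089 transcripts (6.26%) all 4 regenerated libraries lay above all 3 pre-surgery libraries. In 225 (5.50%) all 4 lay below. Chance alone gives 2.86% in each direction. A single transcript cannot reach p under 0.057 by an exact two-sided permutation test on ranks in this design, so these transcripts are not called individually.

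The split between higher and lower transcripts changed with the libraries used. Of the calls with all 8 libraries, 83.6% were higher, and with the replicate block 58.6% were higher. Under the other scalings, 90.4% were higher with DESeq2 size factors and 80.0% with library totals alone. Without the regenerated library of animal 3, 129 transcripts passed, 58 higher and 71 lower (45.0% higher). Leaving out any other single library gave 76.1% to 100% higher.

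**Figure D4:**
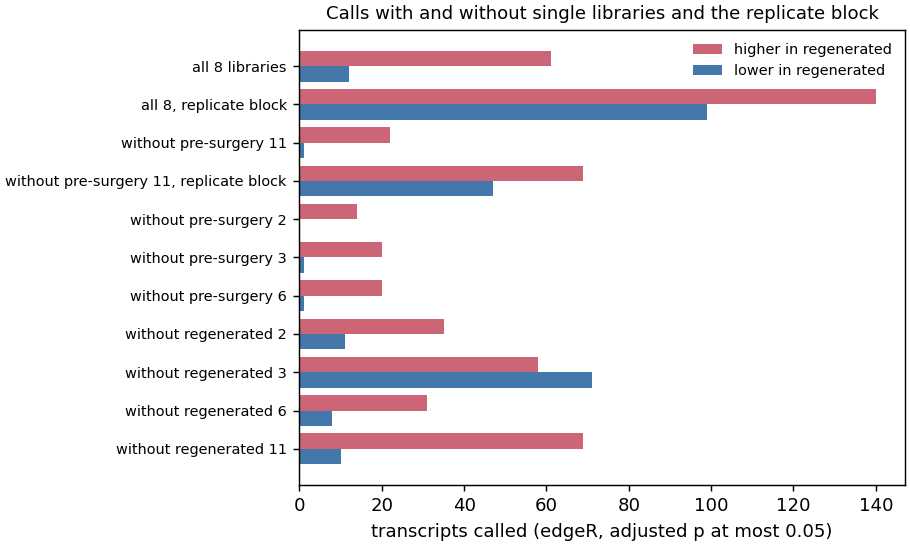
Number of transcripts called higher or lower in regenerated jaw (edgeR, adjusted p at most 0.05) with all 8 libraries, with the replicate block, and with each library left out. The lower calls number 12 with all 8 libraries, 99 with the block and 71 without the regenerated library of animal 3.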

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

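The other scalings and the fit without the regenerated library of animal 3 were planned, but their use as tests of the split between higher and lower calls was chosen after the result was seen. Also chosen after it were the tests of the composition of the near-empty library, of its standard errors and of drawn libraries outside filterByExpr, and those with a filter of 10 counts in 3 libraries, with 1 row per near-identical set or with 2 settings changed together. The normalization factors of 2 libraries stood apart from the other 3 of their group by Dixon's test, out of 14 such tests, where chance flags about 5% of groups. The pre-surgery library of animal 11 had a TMM factor of 3.03, against 0.82 to 0.89. The regenerated library of animal 11 had 0.972, against 0.79 to 0.82.

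The near-empty library, with 489 reads, raised the count of calls in edgeR with filterByExpr from 23 to 73, and on the same 4561 rows, under a filter of 10 counts in 3 libraries, from 22 to 47. It lowered the count with no filter (308 to 200), in DESeq2 (73 to 2) and in limma-voom (37 to 25). Replacing it by 489 reads drawn at random from the other 3 pre-surgery libraries gave, over 20 draws, a median of 73 calls (range 70 to 76) with filterByExpr, 46 to 59 with 10 counts in 3 libraries, 184 to 214 with no filter, 2 to 4 in DESeq2 and 24 to 52 in limma-voom. Depth alone was therefore enough for the change outside limma-voom. There the draws held both 25 and 37, which leaves the question undecided. On the 4561 rows the median ratio of standard errors with the library to those without was 0.928, with 6 against 5 residual degrees of freedom, which is consistent with filtered edgeR counting it as a replicate in the spread without a further measurement. With no filter the ratio was 0.869 although the count fell. There the median prior degrees of freedom, which come from the spread shared between rows, were 47.7 with the library and infinite without it. Smaller standard errors thus did not by themselves bring more calls, and the cause of the falls was not tested.

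In 2 of the 35 splits of the 8 libraries into 4 and 4 the count was at least 73, the real split included, so chance is not excluded for that count. The other such split, with 83 calls, exchanged the near-empty library with the regenerated library of animal 3. Without the near-empty library, 1 of 35 splits gave 23 or more, the real one, and the highest other, which grouped the regenerated library of animal 3 with the pre-surgery libraries, gave 14. No other split that ignores the animals thus reached that count. Such splits mix the pairs, so they do not exclude chance where same-numbered libraries are pairs. Splits that part the pairs number 8, too few for a share under 0.125: the real one gave 73 and the highest other 2 with all libraries, and 23 against 3 without the near-empty library.

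More transcripts were called higher (61) than lower (12). Other scalings of all 8 libraries left at least 80% of calls higher, and 1 row per near-identical set left 83.3%. A filter of 10 counts in 3 libraries without the near-empty library left 100%. These values argue against scaling, near-identical rows and the 4-library filter as the whole cause. DESeq2 size factors use only rows counted in every library, at most the 181 rows of the near-empty library. Other scalings in edgeR were not tried without that library. A part from lower power for falls stays open. Simulated 8-fold falls were recovered in 29.2% of rows and rises in 100%. Without the near-empty library such falls were recovered in 70.9%, yet the calls were more one-sided, 22 higher and 1 lower. Each simulated row started at its pre-surgery level, so a fall left fewer counts than a rise, and filtered rows counted as not recovered. The simulation held no difference between animals. With no filter 81 were higher and 119 lower, 78 of the lower on rows already tested, for a cause not tested. Leaving out the regenerated library of animal 3 gave 45.0% higher, unlike any other single library. This would follow if that library spread the transcripts that are lower in the other 3. That explanation was framed after this result, so the result is no test of it. The share also depended on the pairing. The replicate block gave 58.6% higher with all 8 libraries and 59.5% without the near-empty library in edgeR, and 63.6% and 41.7% in DESeq2. Pre-surgery RNA mixed into the regenerated library of animal 3 would alone move higher and lower calls by the same share. A difference past a bound set beforehand was to count against it. The library's median position was measured from the other regenerated libraries (0) to the pre-surgery libraries (1). It was 0.07 for the 58 higher and 0.73 for the 71 lower calls made without that library. The difference of 0.65 (bootstrap 95% interval 0.50 to 0.82) passed the bound. The same measure gave 0.79 (0.29 to 1.36, on 8 lower calls) for animal 6, 0.24 for animal 2 and -0.11 for animal 11. The library of animal 6 thus passed the bound as well, so passing it cannot decide for or against mixing in animal 3. The interval covers the calls of 1 library and not the spread between animals. Mixing combined with a difference between animals or in the extent of regrowth cannot be told apart from such a difference without it.

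The reads of the near-empty library did not resemble a thin sample of the other pre-surgery libraries. The smallest goodness-of-fit statistic over the 20 rows with the most reads was 376, where the largest of 1000 draws of 489 reads from the library compared was 46.4. Draws of the same size from another library also hold the difference between libraries, and reached at most 87.8 from a deep pre-surgery library and 249 from a regenerated one, 200 draws per pair. Its row ENSXETT00000015711, singled out after its values were seen, took 45 of 489 reads, or 9.20% (95% exact interval 6.79% to 12.1%), against 1.03% to 1.43% in the other 7 libraries. Where its reads came from was not tested, and no biological explanation was tested.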

How the results depend on the processing

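The settings that combine 2 changes, the filter of 10 counts in 3 libraries and the near-identical sets were chosen after seeing the data. The planned count was 73 (61 higher, 12 lower). Totals stayed within 1.5 times of it with DESeq2 size factors, library totals, 10 counts in 4 libraries or 1 row per near-identical set (60). They also did with the block in DESeq2 (77) and without the regenerated library of animal 11 (79). Without the near-empty library, DESeq2 stayed within it without the block (73) and with it (108). So did both fits with 55 calls described below. Similar totals did not always hold the same transcripts. Calls shared with the 73 were 69 with DESeq2 size factors and 59 with library totals. They were 60 each with 10 counts in 4 libraries and with 1 row per near-identical set. They were 53 without the regenerated library of animal 11 and 17 with the block in DESeq2. Without the near-empty library, DESeq2 shared 48 without the block and 31 with it. Those with 55 calls shared 37 and 28, in the order given below. Leaving out 1 library gave 14 to 129 calls, 14 to 69 higher and 0 to 71 lower. The lowest came without the pre-surgery library of animal 2 (14), then animals 3 and 6 (21 each) and 11 (23). Without the regenerated library of animal 2 there were 46, of animal 6 there were 39, and of animal 3 there were 129. The edgeR replicate block gave 239 (140 and 99), and 116 (69 and 47) without the near-empty library. No filter gave 200 (81 and 119). DESeq2 gave 2 (2 and 0), with 40 of 18029 transcripts at an unadjusted p under 0.05, where chance alone would give more. Its low count is therefore no evidence that transcripts did not change. Without the near-empty library 532 reached that p in DESeq2. DESeq2 with the block gave 77 (49 and 28). limma-voom gave 25 (19 and 6), an adjusted p at most 0.01 gave 17 (17 and 0; 505 at an unadjusted p under 0.05), and glmTreat against 1.5-fold gave 14 (14 and 0; 171 at an unadjusted p under 0.05). The filter of 10 counts in 3 libraries gave 47 (41 and 6).

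Without the near-empty library, DESeq2 gave 73 (47 and 26), DESeq2 with the block 108 (45 and 63), limma-voom 37 (28 and 9), no filter 308 (127 and 181), 10 counts in 3 libraries 22 (22 and 0; 563 at an unadjusted p under 0.05), and 1 row per near-identical set 20 (20 and 0; 461 at an unadjusted p under 0.05). Without both libraries of animal 11 there were 55 calls (48 and 7). Without the near-empty library and the regenerated library of animal 3 there were 55 (26 and 29). The cause of these differences was not tested beyond what is said of both libraries above. The 2 named higher transcripts passed in 23 of 24 alternatives with an adjusted p and failed in DESeq2 on all 8 libraries. ENSXETT00000062349 passed in 9 of 25, and ENSXETT00000053959 in 10 of 22. These counts leave out the adjusted p at most 0.01, glmTreat and 1 row per near-identical set. The first 2 of these, and the last without the near-empty library, called 0 lower transcripts. None of the 4 changed sign, in fits that reuse the libraries in which they were chosen. The tests of gene lists and the normalization without muscle and erythroid genes were not run, because no identifier has a gene symbol here. At the depth of the 7 deep libraries, the low-count filter limits the planned comparison to transcripts of about 10 counts or more. With no filter, 22 of the higher and 41 of the lower calls lay on rows outside it.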

Other observations

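Among abundant transcripts, large fold changes were mostly negative, a pattern noticed in the data. Among the 252 tested transcripts with a mean of at least 500 CPM over the deep libraries, 19 rows (13 near-identical sets) had a log2 fold change of -1 or lower, with a median of -1.18. Only 4 rows (3 sets) had one of 1 or higher, with a median of 1.64. The test on all 8 libraries called 2 of the 19. The paired fit without the near-empty library called 15, and the fit without the regenerated library of animal 3 called 14. Of the 4 higher rows these fits called 2, 4 and 2. The 19 rows took 2.50%, 3.72% and 4.21% of counts in the pre-surgery libraries of animals 6, 2 and 3. They took 0.69%, 0.89%, 1.48% and 2.61% in the regenerated libraries of animals 6, 11, 2 and 3. Because the rows were chosen by their fold change, these shares describe the libraries and are no test.

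Animal 3 had the highest share of these 19 rows in both groups. Among the 71 transcripts called lower without its regenerated library, that library lay above the other 3 regenerated libraries in 66. The 71 were chosen as low in those 3, so a library left out of the choice tends to lie above them. The count describes the library and is no test. Its own pre-surgery library stood at a median of 1.33 times the mean of the other 2 deep pre-surgery libraries (quartiles 1.17 and 1.53). For the 58 transcripts called higher that ratio was 0.92 (quartiles 0.74 and 1.22). The fit also without the near-empty library gave 29 lower calls, with a ratio of 1.38.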
